A study of Mus musculus with 30 samples.

How the data were processed

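RNA from the livers of 30 male C57Bl/6 mice was measured on expression microarrays, with 1 biotin-labelled array per liver. The mice had received 1 of 3 piperidine agonists of the nuclear receptor PPAR-alpha at 1 mg/kg per day, or water as vehicle, for 24 h or 5 days. The agonists are known here only by the code names CP-775146, CP-868388 and CP-865520. Each array was placed in 1 of 8 groups from its title, which names the tissue, the time, the treatment and a replicate number. There were 4 arrays in 7 groups and 2 arrays in the group given CP-775146 for 5 days. Each array was taken as a separate mouse, as the series' design text counts mice in these numbers.

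The deposited values are intensities on a linear scale, 1 per probe set and array, and MAS5 is the software named in the submitters' processing notes. Its version, its scaling target and the step that set the lowest value are not given in the sources used here. The deposited intensities are whole numbers from 50 to 29064. The mean over all 12488 probe sets lay between 314.1 and 318.2 on every array, so the arrays had been scaled to nearly 1 mean before deposit. No value lay below 50, and 50.29% of all values were exactly 50, which is called the floor here. A probe set at the floor on every array of a group has only an upper bound in that group, and a fold against it understates the difference. Detection calls were not used here. All 30 columns were used.

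Intensities were analysed as log2(value + 50), where 50 was the 20th percentile of all values. Fold changes are therefore on the log2(value + 50) scale, which understates the change of dim probe sets. No further normalization between arrays was applied. A probe set was kept if it lay above the median of all values, 50, on at least 2 arrays. The 66 control probe sets were left out of the tests, 3977 probe sets never rose above the floor, and 7963 were tested. Among the probe sets other than controls, 4100 lay above the floor on all 30 arrays. The number of arrays limits the precision of every value.

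Group means were fitted to all 30 arrays together with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), so that the group of 2 arrays borrows its spread from the others. Tests were two-sided. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over the 7963 probe sets of a comparison, and a probe set was called at an adjusted p under 0.05. The comparisons were each compound against the vehicle of its time, each pair of compounds at each time, the change of each compound's response from 24 h to 5 days as an interaction, and the vehicle groups of the different times. These comparisons, the model and most alternatives were fixed before the data were examined. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

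The table pairs no probe set with a gene, and the gene table used here lists no array probe sets. The planned gene lists, gene set tests and rule for named genes need gene symbols and were not applied. In their place, 4 probe sets are traced by their IDs. They had to be called in all 6 comparisons with vehicle, with no overlap between compound and vehicle arrays and with intensities above the floor in each group. Of 270 that rose and 278 that fell in this way, those with the largest mean log2 change were taken, 2 in each direction. This rule was chosen after the data were seen. Some control probe sets carry a gene's name in their ID (Gapdh, beta-actin, pyruvate carboxylase, 18S rRNA), and these were tested in the same model with the mouse control probe sets added, also a choice made after the data were seen.

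RNA integrity was followed by the log2 ratio of the 5' to the 3' control probe set of Gapdh, of beta-actin and of pyruvate carboxylase on each array. A lower ratio means less signal from the 5' end of the transcript, as happens with degraded RNA or incomplete labelling. The mean of the 3 standardised ratios was used as a covariate in an alternative model. Another alternative left out the 3 arrays whose Gapdh log2 ratio was under -0.4, a threshold set after the ratios were seen.

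Correlations of log2 fold changes across probe sets and calls in common were set beside the values given by 100 simulations of unchanged groups that share the same vehicle arrays. Correlations were also computed with the 4 vehicle arrays divided so that each compound had 2 vehicle arrays of its own. For each array, a response score was computed as the mean log2 difference from the vehicle arrays of its time over the probe sets called in the same direction under all 3 compounds at the other time. Scores were compared by exact two-sided permutation tests with Benjamini-Hochberg adjustment over 12 tests. This measure was chosen after the data were seen.

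Alternatives were pseudocounts of 1 and 100, no filter and a stricter filter (above 80, the 60th percentile of all values, on at least 4 arrays), quantile normalization, centring on each array's median, smaller sets of arrays in the fit, eBayes without a trend or with robust=TRUE, array weights, a block for the replicate number, and leaving out each array in turn. Centring on the probe sets above the floor on all arrays was added later. No array was a copy of another. Within groups, log2 values correlated at r = 0.968 to 0.990, and at most 1.42% of values above the floor were equal between arrays.

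The procedure was tested on simulated data, with 200 of 7963 probe sets changed by known amounts. Among the brighter probe sets (geometric mean of value + 50 above 200) changed by a log2 of 1, 95.8% were recovered for CP-868388 against vehicle at 24 h, 95.5% for CP-775146 against CP-868388 at 5 days and 100% for CP-868388 against CP-865520 at 5 days. Over all changed probe sets, dim ones included, the shares were 82%, 64% and 90%. At a log2 of 0.5 they were 53.3%, 25% and 35% among the brighter and 48%, 30% and 40% among all. Even at a log2 of 2, the shares among all were 64%, 76% and 80%. For the change from 24 h to 5 days at a log2 of 1, 81.8% of the brighter were recovered with CP-775146 and 85% with CP-868388, and 68% and 70% of all. False calls made up 3.33% to 7.29% of the calls in these simulations, and 0 calls had the wrong direction. Each comparison was simulated 1 time, and the shares given for the brighter rest on 15 to 24 changed probe sets each. The simulated noise was independent between probe sets, with no deviation shared by a whole array. The share of false calls in the real arrays may therefore differ.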

Results

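Liver transcript levels were measured after 3 PPAR-alpha agonists had been given to mice at 1 dose for 24 h or 5 days. PPAR-alpha is a nuclear receptor that controls fatty acid oxidation in the liver, and the series set out to characterize these agonists at the molecular level. Groups held 4 arrays each, except CP-775146 at 5 days with 2. An array had between 5600 and 6741 of 12488 probe sets above the floor of the table, with a mean of 6208 ± 301 (SD, n = 30). Probe sets are given by ID because the table pairs none with a gene, and control probe sets are named where the ID itself carries a gene's name.

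After 24 h, each agonist changed the liver transcriptome against vehicle. The 4 probe sets traced here were chosen for being called in all 6 comparisons with vehicle and for their large mean change, so their values show sizes and are no separate test. The probe set 103581_AT rose from 207 ± 43.0 (SD, n = 4) under vehicle to 4681 ± 223 under CP-775146, 3619 ± 599 under CP-868388 and 4299 ± 492 under CP-865520 (SD, n = 4 each). As ratios of mean intensities, these were increases of 22.6-fold, 17.5-fold and 20.7-fold. The probe set 97316_AT rose from 236 ± 41.7 to 4639 ± 317, 4382 ± 145 and 4262 ± 641 under the same compounds. The probe set 95043_AT fell from 2165 ± 626 under vehicle to 256 ± 57.8 under CP-775146, 525 ± 239 under CP-868388 and 185 ± 18.9 under CP-865520. The probe set 99083_AT fell from 5755 ± 583 to 2330 ± 361, 1668 ± 361 and 2380 ± 288. In 97316_AT, 1 array of CP-865520 stood apart at 5216.

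In all, 1592 probe sets were called under CP-775146 at 24 h (586 higher, 1006 lower), 3234 under CP-868388 (988 higher, 2246 lower) and 1613 under CP-865520 (711 higher, 902 lower). Of these, 94 rose and 92 fell by at least 2-fold under CP-775146, 165 rose and 282 fell under CP-868388, and 79 rose and 101 fell under CP-865520. The arrays of compound and vehicle did not overlap in 1355, 2655 and 1267 of the called probe sets, which the test had picked for a difference. Over all 7963 tested, 23.7%, 35.7% and 21.7% did not overlap, where chance gives 2.86%. A group lay at the floor on all of its arrays in 94, 239 and 89 of the called probe sets, where the floor makes the fold understate the difference. Such a group also has no spread, which lowers the spread used in the test. Some of these calls may therefore be small differences near the floor. All 3 compounds raised 354 probe sets and lowered 672, in comparisons that share the vehicle arrays. The balance of rises and falls depended on the scaling. Quantile normalization gave 1354 higher and 1562 lower under CP-868388. Centring each array on its median gave 794 higher and 631 lower under CP-775146 and 2958 higher and 1253 lower under CP-868388, and moved the median log2 change over all probe sets under CP-868388 from -0.06 to 0.16. Centring on the probe sets above the floor on all arrays gave 2175 higher and 1472 lower under CP-868388.

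RNA integrity differed between these groups. The Gapdh control probe sets had a mean log2 5'/3' ratio of -0.36 ± 0.23 (SD, n = 4) under CP-868388 at 24 h, against 0.02 ± 0.11 under vehicle, 0.03 ± 0.07 under CP-775146 and -0.05 ± 0.27 under CP-865520. Beta-actin gave -1.14 ± 0.21 under CP-868388 and -0.61 ± 0.12 under vehicle, and pyruvate carboxylase -2.76 ± 0.73 and -1.39 ± 0.16. The arrays with a Gapdh log2 ratio under -0.4 were CP-868388 replicate 1 (-0.55) and replicate 3 (-0.55) and CP-865520 replicate 4 (-0.45), all at 24 h. With the integrity covariate, 1538 probe sets were called under CP-868388 against vehicle at 24 h, and without these 3 arrays 2158.

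**Figure D1:**
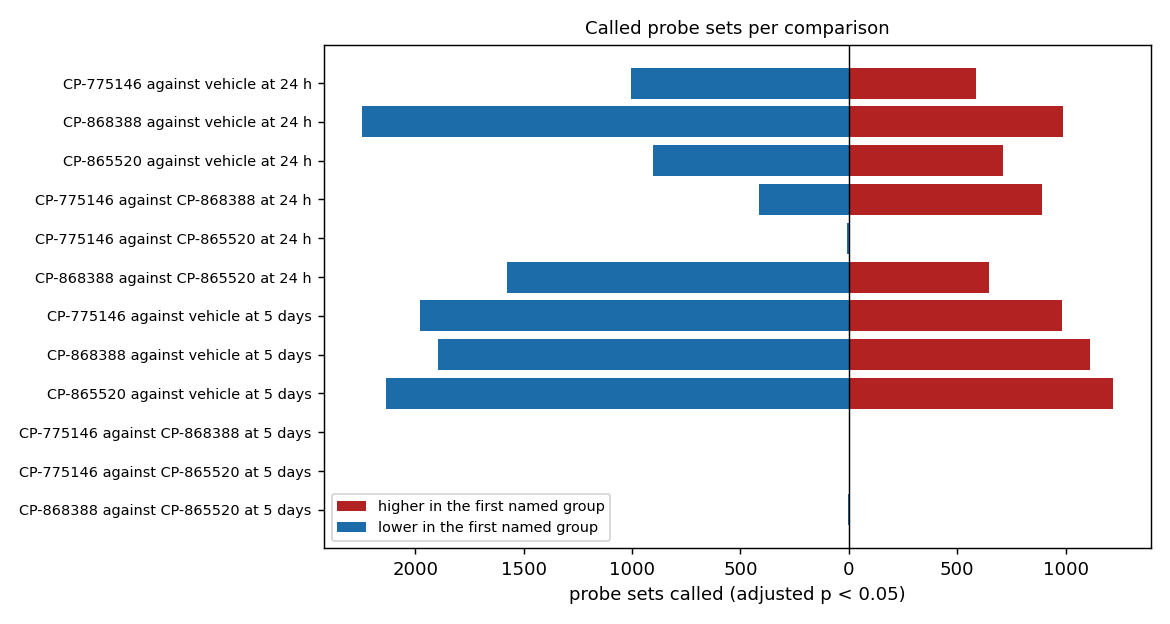
Horizontal bars give the number of probe sets called at a limma adjusted p under 0.05 in each comparison, to the right for those higher and to the left for those lower in the group named first. Comparisons with vehicle reached 1592 to 3355 calls and the pairs of compounds at 5 days 2 to 6, with a split between higher and lower that depends on the scaling.

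Between CP-775146 and CP-865520 at 24 h, 8 probe sets were called, all lower under CP-775146. Over all 7963 tested, the arrays did not overlap in 7.74%, where chance gives 2.86%, and 1022 had an unadjusted limma p under 0.05. The count of 8 was the lowest of the 3 pairs at 24 h, but with the integrity covariate it was 7, against 6 between CP-775146 and CP-868388. The largest of these differences on the log2(value + 50) scale was -0.92, in 93372_AT (51.8 ± 3.50 against 159 ± 93.7, SD, n = 4 each, adjusted p = 0.0452), whose arrays overlapped. Under CP-775146 it lay close to the floor of 50, so its size is uncertain. The next on that scale, on which the order depends, was 160073_I_AT at -0.61 (88.5 ± 11.1 against 161 ± 7.46, adjusted p = 0.0452). Both were chosen after their values were seen, and each call was lost in 15 of 23 alternatives, with adjusted p up to 0.272 and 0.147. On the log2(value + 50) scale, the 95% interval of the difference lay within 2-fold for 98.9% of the 7963 probe sets and for 3214 of the 3270 brighter ones. That scale understates the change of dim probe sets, so a 2-fold difference in intensity is not excluded for these. The count was 41 without CP-865520 replicate 1, 2 without CP-775146 replicate 4 and 0 by limma without CP-775146 replicate 1, 2 or 3 or CP-865520 replicate 2 or 4, where between 761 and 910 probe sets had an unadjusted p under 0.05. Quantile normalization and median centring each gave 1 call, in the opposite direction.

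CP-868388 differed from both other compounds at 24 h. Against CP-775146, 1304 probe sets were called, 891 higher and 413 lower under CP-775146, and 36 of the higher and 3 of the lower reached 2-fold. Against CP-865520, 2223 were called, 647 higher and 1576 lower under CP-868388, of which 11 and 44 reached 2-fold. On the log2(value + 50) scale, the 95% interval lay within 2-fold for 94.5% and 93% of all probe sets and for 2914 and 2838 of the 3270 brighter ones. The probe set 95043_AT, which all 3 compounds lowered, was less depressed under CP-868388 by a log2 of 0.83 than under CP-775146 (CP-775146 minus CP-868388, -0.83 ± 0.23 SE, adjusted p = 0.016) and by 1.19 ± 0.23 (SE) than under CP-865520 (adjusted p = 0.000826). Without the 3 arrays with a 3' bias these differences were -0.36 and 0.74 and the calls were lost, at adjusted p = 0.578 and 0.0652. The first call was lost in 7 of 23 alternatives, among them those with the integrity covariate (-0.52, adjusted p = 0.55) and without CP-868388 replicate 3 (-0.59, 0.109) or 1 (0.0545) or CP-775146 replicate 3 (0.0636), and the second in 2 of 23. Over all alternatives their adjusted p ran from 0.00112 to 0.578 and from 9.36e-05 to 0.0652. The other traced falling probe set, 99083_AT, went the other way. CP-868388 minus CP-865520 was -0.52 (adjusted p = 0.0384, lost in 13 of 23 alternatives, up to 0.316), and CP-775146 minus CP-868388 was 0.48 (0.0722). The rising 103581_AT was higher under CP-775146 than under CP-868388 by 0.38 (0.0351, lost in 13 of 23, up to 0.731).

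Both CP-868388 counts at 24 h depended on the model and on the arrays in it. With the integrity covariate, 6 probe sets were called between CP-775146 and CP-868388 and 521 between CP-868388 and CP-865520. In the second pair, the median absolute log2 difference of the 2223 called probe sets went from 0.49 to 0.35 and its SE from 0.13 to 0.14. Without the 3 arrays with a 3' bias (CP-868388 replicates 1 and 3 and CP-865520 replicate 4) the counts were 38 and 620. Fewer arrays also lower the power, so not all of that fall need come from the bias. Without CP-868388 replicate 3 alone the counts were 462 and 1195. The first count was also 846 without CP-868388 replicate 1, and 821, 738 and 824 without CP-775146 replicates 2, 3 and 4. With only the compared groups in the fit the counts were 388 and 814. Scaling turned the balance of directions. Between CP-775146 and CP-868388, quantile normalization gave 667 higher and 594 lower, median centring 532 and 894 with the median over all probe sets at -0.11, and centring on the probe sets above the floor 571 and 743. Between CP-868388 and CP-865520 the same scalings gave 925 and 774, 2588 and 601 with the median at 0.13, and 1647 and 809.

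**Figure D2:**
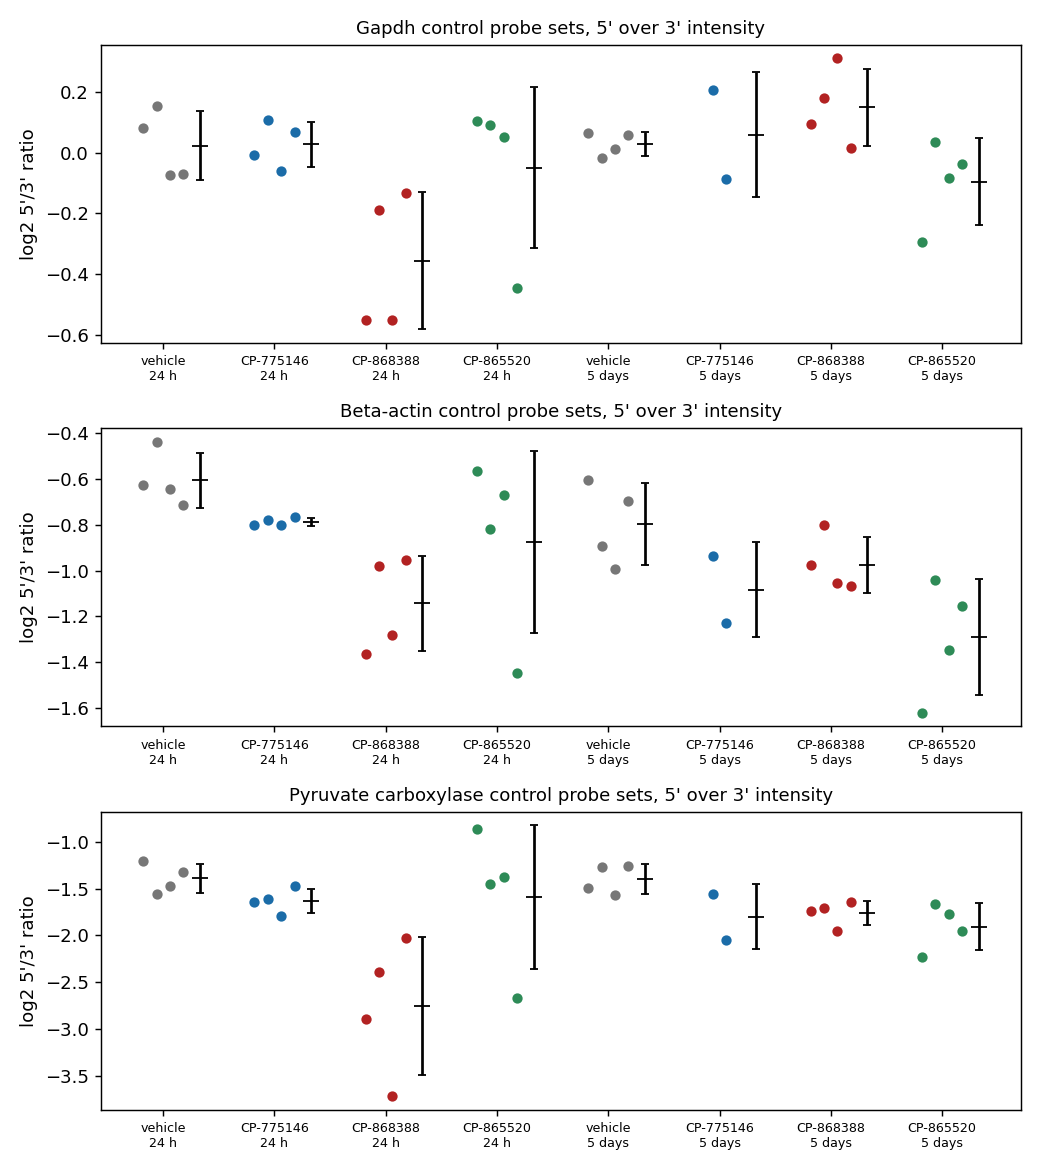
Points are single arrays and give the log2 ratio of the 5' to the 3' control probe set of Gapdh, beta-actin and pyruvate carboxylase, by group, with the group mean and SD in black. CP-868388 at 24 h has the lowest mean for Gapdh (-0.36) and pyruvate carboxylase (-2.76), and CP-865520 replicate 4 at 24 h lies at -0.45 for Gapdh.

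The traced probe sets were chosen on the 5-day values as well. After 5 days 103581_AT was at 205 ± 36.0 under vehicle, 7727 ± 711 under CP-775146 (SD, n = 2), 5706 ± 614 under CP-868388 and 6122 ± 392 under CP-865520 (SD, n = 4). As ratios of mean intensities, the increases were 37.7-fold, 27.8-fold and 29.9-fold. The probe set 97316_AT rose from 168.5 ± 40.7 to 4963 ± 655, 5019 ± 419 and 5254 ± 224. The probe set 95043_AT fell from 1820 ± 336 to 175.5 ± 4.95, 260 ± 83.4 and 191 ± 20.2. The probe set 99083_AT fell from 5350 ± 478 to 409 ± 38.2, 547 ± 89.3 and 331 ± 121.

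**Figure D3:**
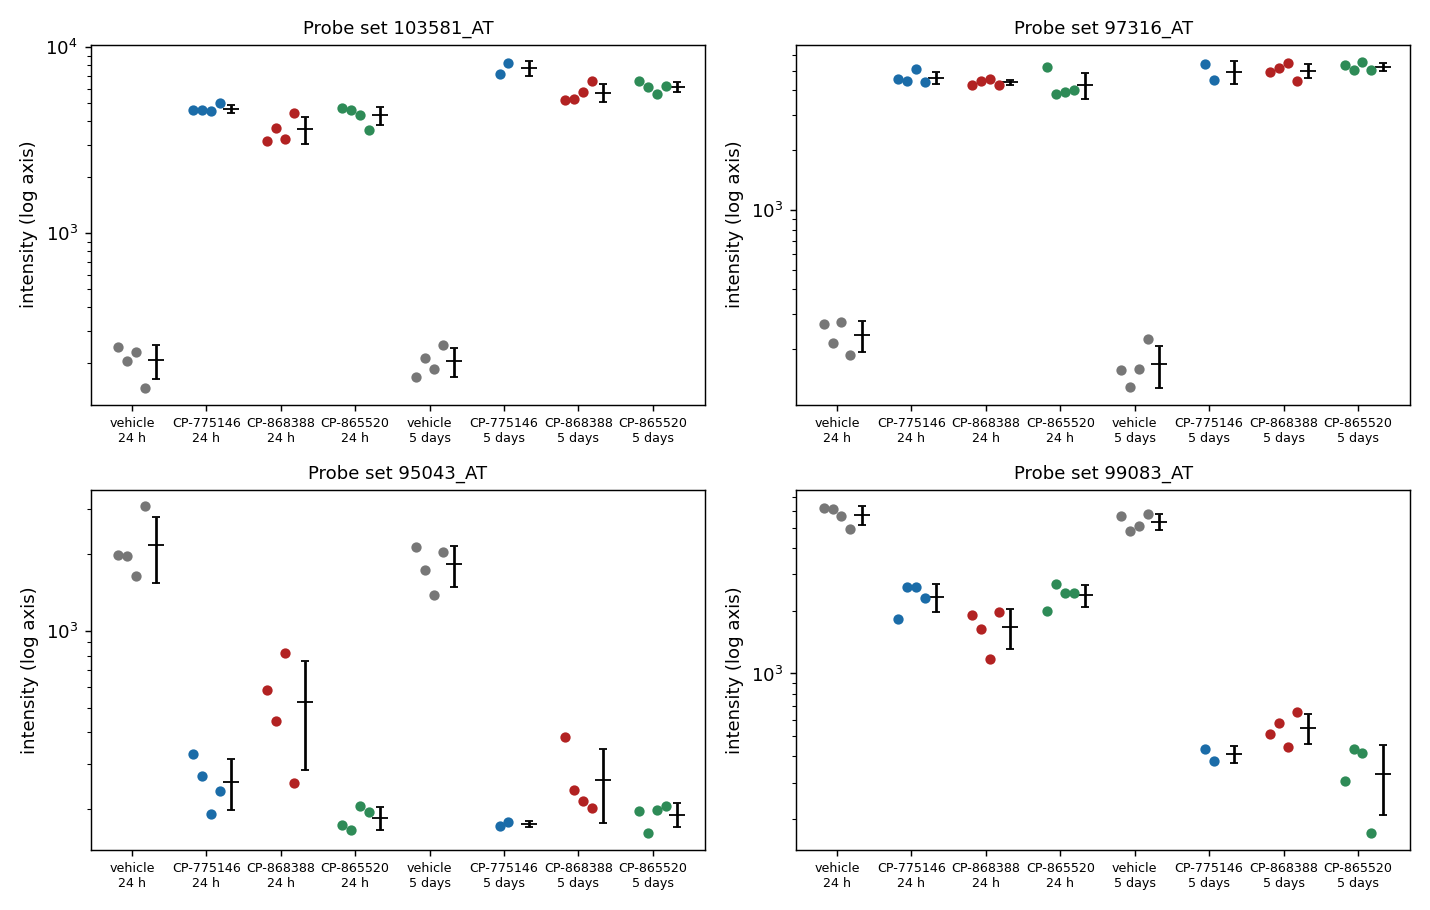
Points are the deposited intensities of single arrays on a log axis for 4 traced probe sets, by group, with the group mean and SD in black. Under the compounds 103581_AT and 97316_AT lie above every vehicle array and 95043_AT and 99083_AT below, and 99083_AT falls further at 5 days, to group means of 331 to 547.

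At 5 days, 2958 probe sets were called under CP-775146 (981 higher, 1977 lower), 3008 under CP-868388 (1114 higher, 1894 lower) and 3355 under CP-865520 (1218 higher, 2137 lower). Changes of at least 2-fold numbered 257 up and 348 down, 211 up and 186 down, and 264 up and 284 down. All 3 compounds raised 851 probe sets and lowered 1446, again against shared vehicle arrays. The arrays did not overlap with vehicle in 2711, 2185 and 2543 of the called probe sets, which were picked for a difference. Over all tested probe sets 43.7%, 29.8% and 33.9% did not overlap, where chance gives 13.3% for 2 arrays against 4 and 2.86% for 4 against 4. A group was at the floor on all its arrays in 353, 229 and 274, where small differences near the floor may again have been called. The median log2 change over all probe sets under CP-775146 was -0.11. Quantile normalization gave 1413 higher and 1278 lower, 1321 and 1357, and 1524 and 1526. Median centring gave 2582 and 970 with the median at 0.13, 2331 and 1059, and 2620 and 1240, and centring on the probe sets above the floor 1944 and 1131, 1352 and 1356, and 1753 and 1441. The CP-775146 count was 1686 without its replicate 2, when its lone other array was assumed to vary like the other groups, and 1734 with only the compared groups in the fit.

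Gapdh, a glycolytic enzyme, and beta-actin, a cytoskeletal protein, are common reference transcripts, and both were lower under every compound at 5 days. The 3' Gapdh control probe set stood at 5686 ± 780 under vehicle (SD, n = 4), 2856 ± 1002 under CP-775146 (n = 2), 3374 ± 1048 under CP-868388 and 3010 ± 590 under CP-865520 (n = 4). It changed by a log2 of -1.02, -0.78 and -0.92, with adjusted p = 0.000503, 0.000862 and 0.000121. The 3' beta-actin control probe set changed by -0.84, -0.62 and -0.81, with adjusted p = 0.00524, 0.00961 and 0.000927. At 5 days the beta-actin log2 5'/3' ratio was -0.80 ± 0.18 under vehicle, -1.08 ± 0.21 under CP-775146 (SD, n = 2), -0.97 ± 0.12 under CP-868388 and -1.29 ± 0.25 under CP-865520 (SD, n = 4). The Gapdh ratio was 0.03 ± 0.04, 0.06 ± 0.20, 0.15 ± 0.13 and -0.10 ± 0.14 in the same order. With the integrity covariate all 6 calls were kept. That covariate is built from the ratios of these same control probe sets. A call kept or lost under it is therefore no separate check on RNA integrity. Directions held under all scalings. The CP-775146 calls were lost without its replicate 2, when Gapdh was at -0.66 and beta-actin at -0.62 (adjusted p = 0.0686 and 0.137, the highest over all alternatives), and the beta-actin call of CP-868388 without its replicate 3 (0.0595) or with only the compared groups in the fit (0.0613). At 24 h, only CP-868388 passed the test, with Gapdh at -0.54 (adjusted p = 0.0131) and beta-actin at -0.61 (0.0102). Both calls were lost with the integrity covariate (0.623 and 0.944), without the 3 arrays with a 3' bias (0.254 and 0.169) and without CP-868388 replicate 3 (0.0731 and 0.057), and the Gapdh call also with median centring (0.0642). The change of the Gapdh response from 24 h to 5 days was called for CP-775146 (-1.03, adjusted p = 0.0303) and CP-865520 (-0.88, 0.0163) and was -0.24 (0.661) for CP-868388. The CP-775146 change was lost in 6 of 28 alternatives (adjusted p from 0.00629 to 0.345), among them those without its 5-day replicate 2 (0.345, when the change was -0.67), its 24 h replicate 3 (0.0526) or 4 (0.0516), or vehicle replicate 1 (0.0561) or 4 (0.0553) at 5 days, and the CP-865520 change was kept in all 30.

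Other control probe sets named for mouse transcripts also moved. Pyruvate carboxylase, a gluconeogenic and anaplerotic enzyme, rose at its 3' control probe set by a log2 of 0.42 under CP-775146 at 24 h (994 ± 117 to 1341 ± 76.0, SD, n = 4, adjusted p = 0.0105). Its 5' control probe set went from 378 ± 21.1 to 435 ± 61.3, with arrays that overlapped. The 3' set did not pass under CP-868388 (-0.07, adjusted p = 0.719) or CP-865520 (0.05, 0.861) at 24 h. This 3' set was lower under CP-865520 at 5 days by -0.31 (adjusted p = 0.0318), a call that 7 of 23 alternatives lost, including both centrings and the integrity covariate, with adjusted p between 0.0171 and 0.301. Its own 5'/3' ratio is part of that covariate, so the covariate is no separate check here. The control probe set whose ID reads MURFAS, for which no gene is assigned here, rose in all 6 comparisons. It went from 62.5 ± 7.94 to 136 ± 8.96, 142.5 ± 21.3 and 108 ± 7.93 at 24 h and from 74.2 ± 16.2 to 172 ± 36.8, 158.5 ± 31.9 and 185 ± 44.2 at 5 days. Its log2 changes were 0.73, 0.77 and 0.49, then 0.84, 0.74 and 0.91, and each passed under every alternative run.

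Between compounds at 5 days few probe sets differed. Between CP-775146 and CP-868388, 6 were called, 5 higher and 1 lower under CP-775146. The lower one was 161176_R_AT (1214 ± 24.8, n = 2, against 2764 ± 282, n = 4, log2 -1.15, adjusted p = 0.00135), and among the higher ones 160567_AT stood at 122.5 ± 6.36 against 55.5 ± 7.55 (log2 0.71, adjusted p = 0.00135). With only the compared groups in the fit both calls were lost (adjusted p = 0.091 and 0.152), and over all alternatives their adjusted p ran from 0.00067 to 0.091 and from 1.08e-06 to 0.176. Between CP-775146 and CP-865520, 2 were called, 104001_AT (61.5 ± 2.12 against the floor of 50) and 97658_F_AT (58 against 50, with an SD of 0 in both groups). Both had an adjusted p = 0.00602 and were small differences close to the floor. Between CP-868388 and CP-865520, 5 were called. Among them 98590_AT was higher under CP-868388 (1077 ± 109 against 708 ± 50.1, SD, n = 4 each, log2 0.57, adjusted p = 0.0353), as was 94644_AT near the floor, and 94302_AT (1992 ± 160 against 2612 ± 182, log2 -0.38, adjusted p = 0.0428) and 93084_AT (-0.45, 0.0353) were lower. These probe sets were singled out after their values were seen. Calls of 98590_AT and 94302_AT were lost in 14 and 15 of 23 alternatives (adjusted p from 0.0103 to 0.315 and from 0.0268 to 0.322), those of 93084_AT in 14 of 23 (up to 0.322) and of 94644_AT in 17 of 22 (up to 0.524), and those of 104001_AT and 97658_F_AT in 6 and 5 of 20.

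These low counts do not show that the compounds act alike. On the log2(value + 50) scale, which understates the change of dim probe sets, the 95% interval of the difference lay within 2-fold for 97%, 97.9% and 98.8% of all probe sets in the 3 pairs at 5 days, and for 3098, 3165 and 3204 of the 3270 brighter ones. The calls were unstable. Leaving out CP-775146 replicate 1 raised the first 2 counts to 201 and 84, leaving out its replicate 2 gave 12 and 7, and leaving out CP-865520 replicate 3 raised the second to 6. The third count fell to between 0 and 2 without CP-868388 replicate 1, 2 or 3 or CP-865520 replicate 1, 2 or 4, and where limma called 0 between 495 and 656 probe sets had an unadjusted p under 0.05. Quantile normalization gave 12 higher and 3 lower between CP-775146 and CP-868388, and 12 and 1 between CP-775146 and CP-865520. Median centring gave 5 and 2 in the first pair, and limma called 0 in each of the others, where 409 and 588 probe sets had an unadjusted p under 0.05.

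The response of each array was also summarised by its mean log2 difference from vehicle over probe sets picked at the other time, a measure chosen after the data were seen. At 24 h, over the 851 probe sets that rose under all compounds at 5 days, CP-868388 scored 0.66 ± 0.09 (SD, n = 4), CP-775146 0.48 ± 0.05 and CP-865520 0.40 ± 0.03. Over the 1446 that fell, the scores were -0.63 ± 0.12, -0.38 ± 0.05 and -0.32 ± 0.07. CP-868388 was the strongest on all 4 of its arrays in both sets. Each of its 4 differences had an exact permutation p = 0.0286, the smallest that 4 against 4 arrays allow, and an adjusted p = 0.0857 over 12 tests, so they did not pass the correction. Its group also had the lowest mean Gapdh 5'/3' ratio. At 5 days the exact permutation p for pairs of compounds ran from 0.143 to 0.667, where 2 against 4 arrays cannot go below 0.0667. CP-868388 minus CP-865520 was -0.09 over the 354 rising probe sets (95% interval -0.25 to 0.07) and 0.10 over the 672 falling ones (-0.05 to 0.26).

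**Figure D4:**
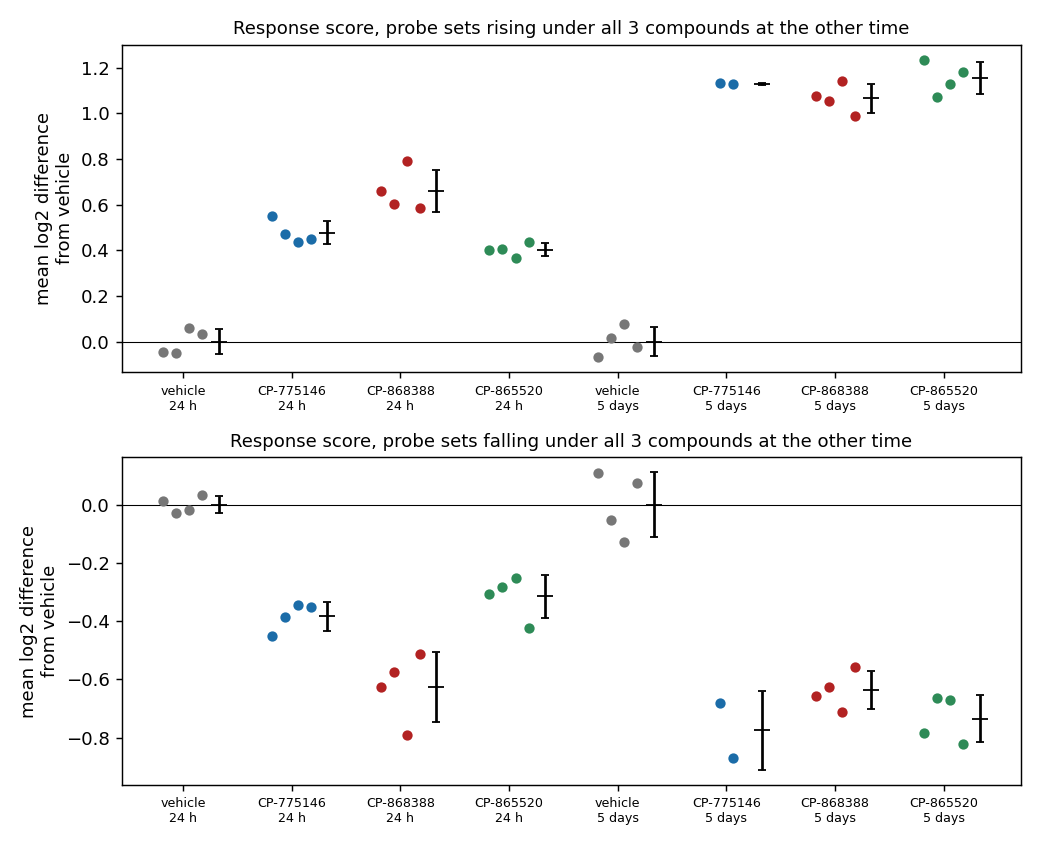
Points are single arrays and give the mean log2 difference from the vehicle arrays of the same time over probe sets that rose (top) or fell (bottom) under all 3 compounds at the other time, with the group mean and SD in black. At 24 h the CP-868388 arrays lie furthest from 0 in both panels, and at 5 days the compounds overlap.

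Across probe sets, the log2 responses of the compounds were similar at both times. At 24 h, r was 0.803 between CP-775146 and CP-868388, 0.888 between CP-775146 and CP-865520 and 0.755 between CP-868388 and CP-865520. At 5 days the values were 0.944, 0.957 and 0.959. Probe sets are not independent replicates, and responses that share vehicle arrays correlate with no effect at all. Simulated unchanged groups gave r of about 0.501 at 24 h and 0.405 to 0.501 at 5 days. The covariances were 0.141, 0.117 and 0.131 at 24 h and 0.263, 0.296 and 0.257 at 5 days, against simulated values between 0.00957 and 0.00968. The difference, which takes out independent noise of the shared arrays, was 0.108 to 0.131 at 24 h and 0.247 to 0.287 at 5 days. It estimates the shared part of the responses only if no deviation was common to whole arrays. The mean integrity covariate was lower in every compound group than in its vehicle, and such a shift would stay in the difference. At 24 h the covariate was 0.36, -1.35 and 0.15 under CP-775146, CP-868388 and CP-865520, against 0.70. At 5 days the values were -0.04, 0.26 and -0.60, against 0.49. With 2 different vehicle arrays for each compound, r was 0.731, 0.792 and 0.684, then 0.875, 0.895 and 0.887. At 5 days, CP-868388 and CP-865520 shared 1003 higher and 1661 lower calls, and 0 probe sets were called in opposite directions. Independent lists of these sizes would share 170 and 508. In 100 simulations of unchanged groups with shared vehicle arrays, limma gave this pair 0 calls in common and a mean of 83.1 probe sets with an unadjusted p under 0.05 in the same direction. The first value leaves out the shared arrays and the second the effects, so the excess over either alone does not measure the shared part. Different compounds at different times share no arrays. CP-775146 at 24 h and CP-868388 at 5 days had 485 higher and 673 lower calls in common and 1 in opposite directions, where independent lists would share 82.0 and 239. For CP-775146 at 24 h and CP-865520 at 5 days these were 498, 709 and 1, against 89.6 and 270 for independent lists. The other pairs of this kind had more opposite calls. CP-868388 at 24 h had 12 with CP-775146 and 10 with CP-865520 at 5 days, where independent lists would give 522 and 609. CP-865520 at 24 h had 42 with CP-775146 and 42 with CP-868388 at 5 days, where independent lists would give 288 and 295.

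The same compound could also be compared across times with no shared arrays. The 24 h and 5-day responses correlated at r = 0.764 for CP-775146, 0.811 for CP-868388 and 0.692 for CP-865520. Over the probe sets called at both times, the slope of the 5-day on the 24 h log2 change was 1.31, 0.95 and 1.28. In all 6 comparisons together, 327 probe sets were called higher and 447 lower, 5012 were called at least once, and 86 were called in opposite directions.

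The change of the response between 24 h and 5 days was tested directly. The probe set 99083_AT fell further at 5 days under each compound, with log2 changes of the response of -2.26 for CP-775146, -1.41 for CP-868388 and -2.63 for CP-865520 and a largest adjusted p of 0.00263, and this held under every alternative run. The probe set 103581_AT rose further by 0.72, 0.66 and 0.52 (adjusted p = 0.0305, 0.0304 and 0.0408), but 9 of 28, 15 of 30 and 17 of 30 alternatives lost these calls, with adjusted p up to 0.206, 0.236 and 0.139. For 97316_AT the change of the response was 0.58 under CP-868388 (0.0408, lost in 18 of 30 alternatives, up to 0.201), 0.70 under CP-865520 (0.00519, kept in all 30) and 0.49 under CP-775146 (0.115). Part of it lay in the vehicle groups, where 97316_AT was lower at 5 days than at 24 h by a log2 of -0.39 (adjusted p = 0.0153, lost in 4 of 22 alternatives, up to 0.134). No change was called for 95043_AT, whose values were -0.20, -0.60 and 0.26 (adjusted p = 0.788, 0.331 and 0.605).

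Over all probe sets, 383 changed their response to CP-775146 (173 higher, 210 lower), 282 to CP-868388 (200 higher, 82 lower) and 1378 to CP-865520 (584 higher, 794 lower). The differences between these counts were not tested. The CP-775146 count was 600 with the integrity covariate, 95 without its 5-day replicate 2, 715 without its 5-day replicate 1, and 238 and 233 without its 24 h replicates 4 and 3. The CP-868388 count was 99 with the covariate, 117 without the 3 arrays with a 3' bias and 184 without its 24 h replicate 1, and the CP-865520 count was 902 without its 5-day replicate 1. Quantile normalization gave 264 higher and 203 lower for CP-775146 and 656 and 513 for CP-865520. Median centring gave 396 and 155, 112 and 84, and 1313 and 359 for the 3 compounds, and centring on the probe sets above the floor 369 and 163, 105 and 90, and 820 and 446.

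The vehicle groups of the different times differed as well. Between vehicle at 5 days and at 24 h, 1807 probe sets were called, 892 higher and 915 lower at 5 days, but 6 of the higher and 7 of the lower reached 2-fold. Of these, which were picked for a difference, 1252 had no overlap between the arrays, as had 21.7% of all tested probe sets, where chance gives 2.86%. The 3' control probe set of 18S ribosomal RNA rose from 376 ± 86.8 to 1771 ± 125 (SD, n = 4 each, log2 2.12, adjusted p = 7.13e-05). At 5 days it was lower than vehicle under CP-868388 (737 ± 272, log2 -1.28, adjusted p = 0.00244) and CP-865520 (650.5 ± 344, -1.54, 0.000337), and the value under CP-775146 was -0.29 (0.606). The count was 1179 without vehicle replicate 2 at 5 days and 1154 with only the vehicle groups in the fit. Time, handling and array batch cannot be told apart in these groups.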

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

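Of the tests in this part, the subtraction of the integrity slope, the test of probe sets where slope and 5-day response point the same way, and both tests on the balance of rises and falls were chosen after the result was seen, as were the covariate and the omission of 3 arrays. The bound for the share of the 100 brightest was also restated after its result was seen, to require a difference beyond the SD, and this changed the verdict from argued against to open.

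Among 105 groups of values examined, 4 held an array far from the others of its group, and chance gives about 1 in 20. CP-868388 replicate 3 at 5 days had 5714 probe sets above the floor, where the others had 6122 to 6204. CP-865520 replicate 4 at 24 h had a Gapdh log2 5'/3' ratio of -0.45, where the others lay between 0.05 and 0.10. In CP-865520 at 24 h, 97316_AT stood at 5216 on replicate 1 and at 3856 to 4036 on the others. In vehicle at 5 days, the control probe set whose ID reads MURFAS was at the floor of 50 on replicate 1 and at 81 to 84 on the others.

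Responses that differed between 24 h and 5 days by the interaction test numbered 383 for CP-775146, 282 for CP-868388 and 1378 for CP-865520. Among the traced probe sets, the differences were 0.72 (103581_AT) and -2.26 (99083_AT) under CP-775146, 0.66 (103581_AT), 0.58 (97316_AT) and -1.41 (99083_AT) under CP-868388, and 0.52 (103581_AT), 0.70 (97316_AT) and -2.63 (99083_AT) under CP-865520.

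CP-868388 differed from CP-775146 at 24 h in 1304 probe sets. A stronger early response to CP-868388 as the whole account stays open. In 230 called probe sets, the integrity slope of the other 6 groups and the 5-day response to CP-865520 point opposite ways. Of these, 33.5% (77) followed the 5-day response, a share under the bound set in advance as arguing against that account. The test still cannot decide, because its reference was another compound, whose 5-day group itself had lower RNA integrity than vehicle. The mean integrity covariate was -0.60 ± 0.65 under CP-865520 and 0.49 ± 0.29 under vehicle at that time (SD, n = 4 each). Lower RNA integrity may account for much of the difference, since the fold changes correlated at r = 0.75 (0.511 over all tested probe sets) with the deviation of CP-865520 replicate 4, an array of another group with a 3' bias, and subtracting the slope left 519 calls. That array was also among those that gave the slope, so the 2 results are not independent. A slope fitted without it correlated with the fold changes at r = 0.782 across the called probe sets. With the covariate, the median absolute log2 difference of these probe sets went from 0.51 to 0.29 and its SE from 0.14 to 0.15, so that the loss of calls came mostly from smaller differences. In the 1069 probe sets where slope and 5-day response point the same way, 2.25% went against both, and there integrity and an early response cannot be told apart because both predict the same sign.

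More probe sets were called lower than higher under the compounds, with 30.6% higher at the lowest under CP-868388 at 24 h. A few abundant probe sets taking more of a fixed total stays open, as the 100 brightest held a larger mean share of the signal than under vehicle in 2 of the 6 comparisons, beyond the SD only for CP-868388 at 24 h (27.6% against 25.2%), and a lower one, within the SD, in the other 4. The scaling of each array to 1 mean could also produce such an imbalance. Centring on the probe sets above the floor on all arrays turned CP-868388 at 24 h to 59.6% higher and gave 44.9% to 63.2% over the 6 comparisons. Centring evens or turns the split by itself, so scaling, abundant probe sets and a true excess of falls cannot be told apart here.

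Vehicle at 5 days differed from vehicle at 24 h in 1807 probe sets. Across these, the difference between the compound groups of the same times correlated with the vehicle difference at r = 0.753, which is consistent with a shift of all arrays of a time. The labels separate neither age, handling nor array batch from time, so whether that shift is biological was not tested.

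The same arrays were also split in other ways and refitted. In each of the following, 1 of 35 splits, the real one, reached the real count. This is the smallest share the arrays allow, and it excludes chance at 0.05 for each test alone, with no correction over the 12 tests. The real count and the highest of the others were 1592 and 22 for CP-775146 against vehicle at 24 h, 3234 and 6 for CP-868388, 1613 and 26 for CP-865520, 3008 and 1329 for CP-868388 against vehicle at 5 days, and 3355 and 1347 for CP-865520. At 24 h they were 1304 and 402 for CP-775146 against CP-868388, 8 and 6 for CP-775146 against CP-865520, and 2223 and 1243 for CP-868388 against CP-865520. They were 1807 and 158 for the vehicle groups. The count of 8 rests on single arrays, since it fell to 0 without CP-775146 replicate 1, 2 or 3 or CP-865520 replicate 2 or 4, where limma gave between 761 and 910 probe sets an unadjusted p under 0.05. Chance is not excluded for CP-868388 against CP-865520 at 5 days, where 2 of 35 splits, the real one included, reached 5 calls and the highest other gave 8. Nor is it excluded for the change of the CP-868388 response. There 5 of 100 splits, the real one included, reached 282 and the highest other gave 1441. For the change of the CP-865520 response, 3 of 100 splits, the real one included, reached 1378. That share is under 0.05, but the highest other gave 2488, above the real count. Splits for the changes mix compound and vehicle arrays and carry the compound effect, a structure of the samples that raises their counts. They do not stand for an unchanged response, so this test does not decide on chance for the changes. Comparisons with the 2 arrays of CP-775146 at 5 days had too few arrays for this test.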

How the results depend on the processing

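The tests with the integrity covariate, without the 3 arrays with a 3' bias and with centring on the probe sets above the floor on all arrays were chosen after the data were seen, as were the traced probe sets, the control probe sets and the response score.

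Directions of the traced probe sets against vehicle and their side of the threshold held under every alternative, but these were chosen for calls in all 6 comparisons. Those of the MURFAS control and of the called 18S results held as well. Against vehicle, calls were lost in 5 of the Gapdh, 6 of the beta-actin and 7 of the pyruvate carboxylase alternatives, and no called result reversed. Leaving out 1 of the 2 arrays of CP-775146 at 5 days leaves a lone array, which is then assumed to vary like the other groups. The counts against vehicle stayed within 1.5 times of their value except as listed here. The cause of these moves was not tested.

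With the integrity covariate, counts became 1538 for CP-868388 against vehicle at 24 h, 6 for CP-775146 against CP-868388 at 24 h, 521 and 3 for CP-868388 against CP-865520 at 24 h and 5 days, and 600 and 99 for the changes of the CP-775146 and CP-868388 responses. Without the 3 arrays with a 3' bias they were 38, 0 and 620 for CP-775146 against CP-868388, CP-775146 against CP-865520 and CP-868388 against CP-865520 at 24 h, 4 and 10 for CP-775146 and CP-868388 against CP-865520 at 5 days, and 117 for the change of the CP-868388 response. With only the compared groups in the fit they were 388, 3 and 814 for the 24 h pairs in the same order, 1734 for CP-775146 against vehicle at 5 days, 0 for CP-868388 against CP-865520 at 5 days and 1154 for the vehicle groups.

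With all arrays in the data, the remaining moves of counts were in pairs with 8 calls or fewer. CP-775146 against CP-865520 at 24 h gave 148 with array weights, 32 without an intensity trend, 17 with the stricter filter, 14 with only the arrays of that time, 1 with median centring or quantile normalization, and 0 with no filter or with centring on the probe sets above the floor. At 5 days it gave 13 with quantile normalization, 1 with robust=TRUE or with only the arrays of that time, and 0 with the stricter filter, without a trend or with either centring. CP-775146 against CP-868388 at 5 days gave 15 with quantile normalization and 3 with the stricter filter or only the arrays of that time. CP-868388 against CP-865520 at 5 days gave 17 with array weights and 0 with the stricter filter, robust=TRUE, only the arrays of that time or either centring. Where limma called 0, between 304 and 1034 probe sets had an unadjusted p under 0.05.

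With each array left out in turn, counts at 24 h ran from 462 to 1592 for CP-775146 against CP-868388 (lowest without CP-868388 replicate 3), 0 to 41 for CP-775146 against CP-865520 and 1195 to 2345 for CP-868388 against CP-865520. At 5 days they ran from 1686 to 3085 for CP-775146 against vehicle (lowest without CP-775146 replicate 2), 5 to 201 and 2 to 84 for CP-775146 against CP-868388 and CP-865520 (highest without CP-775146 replicate 1), and 0 to 7 for CP-868388 against CP-865520. The changes ran from 95 to 715, 184 to 365 and 902 to 1476 for CP-775146, CP-868388 and CP-865520, and the vehicle groups from 1179 to 2016. The other counts ran from 1235 to 1459, 2684 to 3253 and 1296 to 1547 for the compounds against vehicle at 24 h, and from 2467 to 3064 and 2922 to 3342 for CP-868388 and CP-865520 at 5 days.

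With 2 different vehicle arrays for each compound, r fell to 0.731 and 0.792 for CP-775146 with CP-868388 and CP-865520 at 24 h, and to 0.875, 0.895 and 0.887 for the pairs at 5 days. Each compound then also had 2 vehicle arrays and not 4. A pseudocount of 1 gave 0.857 for CP-775146 with CP-865520 at 24 h.

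Replicate numbers did not pair the arrays. Deviations of arrays with the same number correlated at a mean of -0.03 at both times, and over 0.1 in 3 of 24 pairs at 24 h and 4 of 18 at 5 days. With the replicate number as a block, counts at 24 h were 1531, 3201 and 1530 against vehicle and 1195, 0 and 2103 between compounds. At 5 days they were 2876, 2945 and 3307, then 6, 2 and 1. The changes gave 345, 233 and 1291, and the vehicle groups 1674.

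The alternatives for gene list shifts and for named genes were not run, since both need gene symbols. Signal limits what can be seen, as 50.29% of all values lay at the floor.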
